A study of Drosophila melanogaster with 32 samples.

How the data were processed

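Whole-fly RNA of mated female Drosophila melanogaster was measured on 32 single-colour Affymetrix Drosophila Genome 2.0 arrays, a platform named from the array file names per the labels. The flies came from 8 laboratory populations founded from the LHM base stock. In 4 populations each female mated with a single male per generation (monogamy) and 4 were kept under the standard protocol with multiple mating (promiscuity). After 46 generations, females of each population were crossed to males of their own population and to males of the same-numbered population of the other regime, and were frozen 6 h after mating. This gave 16 crosses with 2 arrays each, 1 in each of 2 batches, so the batch and the replicate array of a cross cannot be told apart. Each batch held all 4 combinations of female and male regime.

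The deposited values were on the log2 scale and had been computed with RMA and the affy package, per the submitters' processing notes, which gave no version. RMA subtracts background, forces the arrays onto a shared distribution of intensities and summarises the probes of a set, so a change that moved most genes by the same amount would not be visible, and weak probe sets are drawn towards the background level. No further normalization was applied. The table held 18952 probe sets with no missing value. The 183 control probe sets were left out and 18769 were tested. Genes were named from the platform annotation, which is old: 13647 of the tested probe sets had 1 gene, 402 had several and 4720 had none, and no gene was named from a probe set with several. The 13647 covered 11983 genes, and 13544 of them were matched to a RefSeq gene table of the Release 6 plus ISO1 MT assembly, which was used only for current names and for the order of genes. Probe sets assigned to near-identical gene copies can cross-hybridise. For arrays there is no read depth, and the number of arrays and populations limits the precision.

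The population was taken as the unit of replication because it is the unit that evolved. For the female regime, the 4 arrays of each female population were averaged, which balances batch and male regime, and 4 promiscuous were compared with 4 monogamous populations. For the male regime, a response was computed in each female population as the mean of its 2 arrays with promiscuous-line males minus the mean of its 2 arrays with monogamous-line males, so that batch cancels. The 8 responses were fitted together with female regime as a term. That fit tested the mean response over both female regimes, the mean response within each female regime, and the difference between the 2 female regimes (the interaction). Crosses within a population were compared between regimes as 4 against 4 cross means. In those crosses both sexes came from 1 population, so sharing a regime and sharing a population are 1 contrast. Populations of a number shared their 2 male populations across the 2 female regimes, so the 8 responses rest on 4 independent pairs of male populations. The batch was tested on the differences within the 16 crosses.

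All fits used limma 3.58.1 in R 4.3.3 with lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. By chance 938 of the tested probe sets lie under an unadjusted p of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Of 29 lists, 28 had members on the array. The mean of each list was also compared between populations with an exact permutation test, or an exact sign-flip test for responses, both two-sided. The smallest p these can give is 0.0286 for 4 against 4 populations, 0.00781 for 8 responses and 0.125 for 4 responses, so a test within 1 female regime cannot reach 0.05. The tests of 8 responses treat them as independent, and turning the 2 responses of a number together allows no p below 0.125. List p-values were adjusted over the 28 lists of a comparison. The comparisons, the lists, the tests and the alternatives were fixed before the data were examined, except where a test is said to have been chosen later. The lists were antimicrobial peptides, immune recognition and signalling, Turandot and heat shock genes, eggshell, yolk and fat body, germline and early oogenesis, post-mating switch and ovulation, spermatheca and female tract secretory genes, male accessory gland seminal proteins, testis and sperm, gut digestive enzymes, phototransduction and eye, odorant-binding proteins, chemosensory receptors, neuronal, muscle, juvenile hormone and ecdysone, insulin and nutrient signalling, lipid metabolism, cytochrome P450, glutathione transferases, UDP-glycosyltransferases, cuticular proteins, cytoplasmic ribosomal proteins, proteasome, cell cycle and replication, sex determination and circadian clock. A list of mitochondrially encoded genes had no member on the array. The lists held 1003 genes, of which 12 stood in more than 1 list.

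Genes were named by a rule. Probe sets past the threshold that had a single gene and the same sign in every population number were named, up to 10 in each direction. Where fewer than 10 probe sets passed, all of those were named, and the 5 smallest unadjusted p-values were given as values that did not pass. From each list, up to 4 members past the threshold over all probe sets or adjusted over the list alone were named, and otherwise the 2 with the smallest p as values. Each gene is represented by its probe set with the smallest p. Adjustment over a list alone covers the probe sets of that list, and not the number of lists or comparisons, so some members pass by chance.

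The tests were checked on simulated data, drawn independently for each of the 18769 probe sets with the spread of the real values. Of known differences added to them, limma recovered 97% of differences of 0.5 log2 in the female regime and 80.6% in the interaction, and 98.5% of differences of 0.5 in the mean response to male regime. In the crosses within populations 76.1% of differences of 0.5 and 95.5% of differences of 1 were recovered. At most 10 unchanged probe sets were called in a comparison. Each run held 66 or 67 changed probe sets of each size. With fewer changed probe sets the adjustment is stricter, so a smaller share would be recovered. In the real female comparison 17 probe sets differed by more than 1 log2 and 0 passed. A count of 0 therefore does not exclude differences of 0.5. Camera was also run on simulated data with a shifted list, but simulated probe sets were independent, so that run does not test how camera deals with correlated genes.

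Arrays correlated with each other at 0.9922 to 0.9982 across probe sets, and no 2 arrays held identical values. The 2 arrays of a cross differed by a root mean square of 0.1928 to 0.257 log2. The median SD over probe sets was 0.1172 between the arrays of a cross after batch, 0.0684 between population means of a regime and 0.1036 between responses. The first is for single arrays, the second for means of 4 arrays and the third for differences between means of 2 arrays. Their sizes therefore cannot be ranked against each other, and noise of the arrays enters all of them. The labels number the populations 1 to 4 in both regimes. The deviations of same-numbered populations from their regime mean correlated at 0.13, 0.07, 0.19 and 0.02. The highest correlations with another number were 0.09, 0.04, 0.04 and 0.09. These values are low, and the main female comparison was not paired by number, although same-numbered females were mated to the same 2 male populations. For the responses the number marks shared male populations by design, with correlations of 0.17, 0.03, -0.04 and 0.01, and the fit with the number as a block is given beside a male result where it changes the count.

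The alternatives were each batch alone, the number as a block, all 32 arrays as samples with batch as a term and the female population as a block, array weights, quantile normalization on top, centring of each array on its median, leaving out the dimmest 40% of probe sets, eBayes without the trend, averaging per gene, a threshold of 0.1, and leaving out each population in turn.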

Results

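Post-mating expression was measured in females of 8 fruit fly populations that had evolved for 46 generations under monogamy or under promiscuity. Monogamy removes competition between the ejaculates of different males and female choice among them, so the crosses ask how the evolutionary history of each sex bears on the state of females 6 h after mating. Females of 4 monogamous and 4 promiscuous populations were each mated to males of either regime. The 16 crosses had 2 arrays each, giving 32 arrays, 8 for each combination of female and male regime. Array medians and quartiles were alike after the deposited RMA step, and values below are log2 with n counting populations.

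The first comparison asked whether females from the 2 regimes differed, whatever their mate. Some members of the gut enzyme, insulin and lipid lists passed a test within their list, while these lists as a whole were not called. Mal-B1, a maltase of the alpha-glucosidase family, averaged 7.67 ± 0.21 (SD, n = 4) in monogamous and 6.45 ± 0.53 (SD, n = 4) in promiscuous populations. The difference was -1.22 with an SE of 0.24. The alpha-glucosidase gene tobi, a target of insulin and glucagon-like signals, averaged 10.41 ± 0.23 (SD, n = 4) in monogamous and 9.57 ± 0.33 (SD, n = 4) in promiscuous females. The fatty acid desaturase Desat1 differed by -0.19 and the acetyl-CoA synthetase AcCoAS by -0.22, both lower in promiscuous females, while the activin-like ligand daw was higher by 0.29. These 5 genes passed when adjusted over the list alone, with limma adjusted p-values of 0.0235 for Mal-B1, 0.011 for tobi, 0.0121 for Desat1, 0.0289 for AcCoAS and 0.0241 for daw. None passed over all probe sets, where each had an adjusted p of 0.554.

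Germline and early oogenesis genes were lower in promiscuous females as a group. Of 40 probe sets 33 were lower, with a median difference of -0.05, and the list mean was lower in all 4 population numbers (exact permutation p = 0.0286 before and 0.638 after adjustment over lists). The translational repressor pum was at -0.14 and the cyclin CycE at -0.18, and no member passed when adjusted over the list alone. Fry called no list for the female regime. Camera gave the germline list an adjusted p of 3.36e-06, against an adjusted p of 0.33 with an estimated correlation. The median was -0.02 in batch 1, where the call was lost, and -0.07 in batch 2. Phototransduction and eye genes were higher, with 26 of 35 probe sets above 0 and a median of 0.06 (camera adjusted p = 0.00479, and 0.822 with an estimated correlation). In that list chaoptin, chp, a photoreceptor surface protein, was higher by 0.28 with an SE of 0.05 and passed adjusted over the list alone (limma adjusted p = 0.0173). The list median was 0.08 in batch 1 and 0.03 in batch 2, where its adjusted p was 0.252. The clock gene tim was higher by 0.47 and passed adjusted over the list alone (limma adjusted p = 0.046), although a second tim probe set was at -0.03.

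Over all 18769 probe sets limma called 0 for the female regime at an adjusted p of 0.05, with 1334 under an unadjusted p of 0.05 against 938 by chance and a smallest adjusted p of 0.554. The smallest unadjusted p-values belonged to wat, an acyl-CoA reductase gene, at 0.33 with an SE of 0.05, to CG3609 at -0.32, to CG40485 at -0.87, to the zinc transporter gene Zip102B at -1.08 with an SE of 0.18, and to CG33281 at 0.45. Each had the same direction in all 4 population numbers. A second probe set of CG40485 was at 0.19, the opposite direction. Treating all 32 arrays as samples gave 142 probe sets, 104 higher and 38 lower, with arrays of a population counted as correlated. Another split of the populations gave 256 in the same way, so chance could not be excluded for that count.

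The second comparison asked how the males' regime of origin bore on the females they mated with. Antimicrobial peptide genes were lower after mating with promiscuous-line males, in 19 of 22 probe sets with a median of -0.18. Camera gave the list an adjusted p of 1.74e-06, against an adjusted p of 0.417 with an estimated correlation. Adjusted over the list alone 6 passed, all lower. Among these, the drosomycin-like genes Drsl4 and Drsl5 responded by -0.36 with an SE of 0.07 and by -0.13, the infection-induced gene edin by -0.37 with an SE of 0.11, and the bomanin gene BomT3 by -0.23. Of these edin was lower in all 8 female populations, with a mean of -0.23 without monogamous population 1, where its response was -1.28. In the list of immune recognition and signalling genes, PGRP-SB1, which encodes a peptidoglycan recognition protein, responded by -0.49 with an SE of 0.12 and pirk, a negative regulator of the Imd pathway, by -0.24 with an SE of 0.06, again lower in 8 of 8 populations. Both passed adjusted over the list alone. The list as a whole did not pass, with 18 probe sets higher and 21 lower (median -0.01, camera adjusted p = 0.342).

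The mean of the antimicrobial peptide list averaged -0.24 ± 0.32 (SD, n = 8) and was lower in 6 of 8 populations. The exact sign-flip p was 0.0781, and 0.25 with the 2 responses of a number turned together. The median was -0.22 in batch 1 and -0.10 in batch 2. Population number 1 carried much of the size: its responses were -0.79 in monogamous and -0.55 in promiscuous females. Without it the mean was -0.09, with an exact sign-flip p of 0.312, and 0.5 with numbers turned together. The batches differed in this. In batch 2 the list mean responded by -1.04 and -0.85 in number 1 and by -0.2 to 0.34 in the other populations. In batch 1 it responded by -0.54 and -0.24 in number 1, within the -0.69 to 0.08 of the other populations.

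Digestive enzymes of the gut were also lower, 36 of 44 probe sets with a median of -0.06, of which 3 passed adjusted over the list alone. The list mean was lower in 6 of 8 populations (exact sign-flip p = 0.0547). The trypsin gene betaTry responded by -0.07, and the serine protease genes Jon99Ci and Jon25Biii by -0.10 and -0.08. The camera adjusted p was 1.59e-05, against an adjusted p of 0.417 with an estimated correlation, and the batch medians were -0.07 and -0.05. Germline and early oogenesis genes were higher in 37 of 40 probe sets, with a median of 0.05, in 7 of 8 populations (exact sign-flip p = 0.0156, and 0.218 after adjustment over lists). Its members oskar, osk, and ovo responded by 0.16 and 0.10, and none passed adjusted over the list alone. The camera adjusted p was 2.57e-07, against an adjusted p of 0.417 with an estimated correlation, with batch medians of 0.06 and 0.05.

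Smaller shifts were called in 6 further lists. Neuronal genes were higher by a median of 0.04, with the potassium channel gene Shal at 0.16 and the synaptic SNARE gene Snap25 at 0.10 past the test adjusted over the list alone. Cell cycle genes were higher in 18 of 19 probe sets, with a median of 0.03. Muscle genes were higher by a median of 0.02, with 8 probe sets past adjusted over the list alone, among them bt and sls, which encode giant proteins of the sarcomere, at 0.15 and 0.21. Seminal protein genes were lower by a median of -0.03, chemosensory receptors by -0.02 and cuticular proteins by -0.02. With an estimated correlation the adjusted p-values of these 6 were 0.417 to 0.668, so that none of the 9 lists was called. The list mean kept its direction in 5 of 8 populations for muscle and cell cycle genes (exact sign-flip p = 0.375 and 0.203). It did so in 7 of 8 for neuronal genes (0.0703). For seminal proteins, chemosensory receptors and cuticular proteins it did so in 6 of 8 (0.0703, 0.0859 and 0.0469). No exact p was under 0.218 after adjustment over lists. The muscle median was -0.02 in batch 1 and 0.10 in batch 2. Neuronal genes were at 0.09 and 0.02 in the 2 batches, cell cycle genes at 0.03 and 0.04, seminal protein genes at -0.04 in both, chemosensory receptors at -0.03 and -0.02, and cuticular proteins at -0.04 and -0.01. Leaving out the dimmest 40% of probe sets ended the calls of chemosensory receptors (adjusted p = 0.249) and seminal proteins (adjusted p = 0.189).

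A pair of genes in the eggshell list moved more. The follicle cell gene Fcp3C responded by 0.79 with an SE of 0.16 and was higher in 8 of 8 populations, and CG14187 by 0.55 with an SE of 0.10, higher in 7 of 8. Both passed adjusted over the list alone, while the list itself had a median of 0.01 (camera adjusted p = 0.911). Fcp3C was at 1.08 in batch 1 and 0.49 in batch 2, and CG14187 at 0.72 and 0.37. Other members past their own list alone were retinin, a protein of the corneal lens, at -0.13, the glutathione transferase GstE5 at -0.16, both lower in 8 of 8 populations, and the sex determination gene Sxl at 0.22, whose other probe sets lay at 0.01 to 0.07. The sex determination list was the only list fry called here (adjusted p = 0.0229). Its mean was higher in 8 of 8 populations (exact sign-flip p = 0.00781, and 0.218 after adjustment over lists) with a median of 0.03, and camera did not call it (adjusted p = 0.0522).

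Over all probe sets limma called 0 for the mean response to male regime, with 2057 under an unadjusted p of 0.05 against 938 by chance and a smallest adjusted p of 0.219. With the population number as a fixed block, 13 probe sets passed, 2 higher and 11 lower. That fit tests the mean response against the spread within numbers. Differences among the pairs of male populations do not count as error there, so these calls hold for the male populations used. Fcp3C (blocked adjusted p = 0.00754) and CG14187 (0.00916) were higher. The named genes among the lower were CG16713, PGRP-SB1, BomBc2, BomBc3 and BomT3, with blocked adjusted p-values of 0.00916, 0.021, 0.0459, 0.0275 and 0.019. These rest largely on number 1: their mean responses of -0.28, -0.49, -0.48, -0.49 and -0.23 were -0.10, -0.30, -0.07, -0.21 and -0.10 without it. BomBc2 and CG16713 were above 0 in both populations of number 3. When the responses of each number were averaged first, leaving 4 values with the pair of male populations as the sample, 0 passed.

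**Figure D1:**
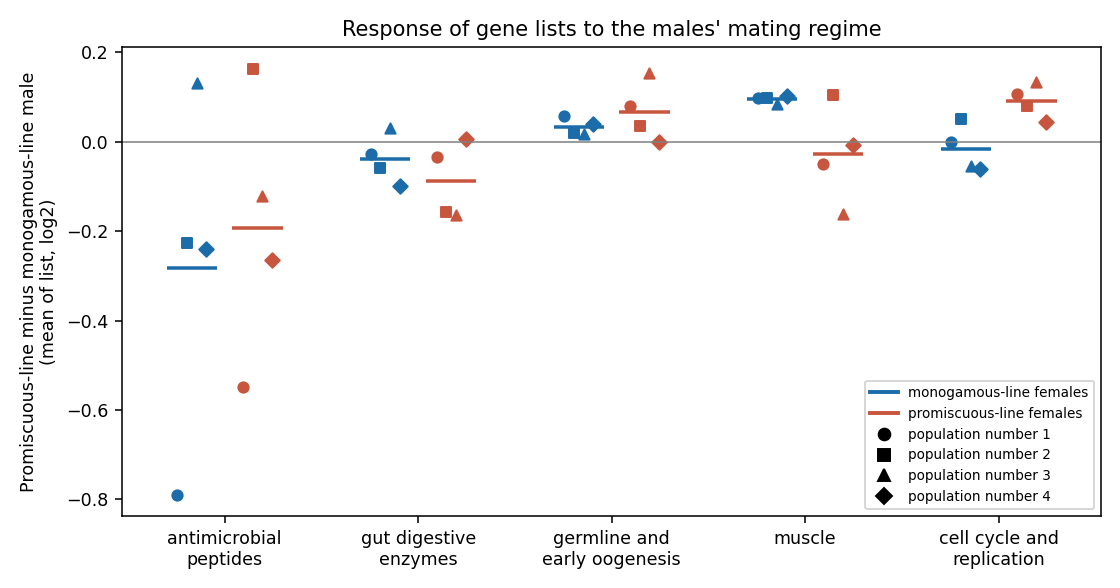
Response of 5 gene lists to the males' regime, as the mean log2 difference between mating with promiscuous-line and with monogamous-line males, with a point per female population (blue monogamous, red promiscuous, shape for population number) and a bar for the mean of 4. The antimicrobial peptide responses of number 1 lay lowest, at -0.79 and -0.55, and the cell cycle responses of the promiscuous populations lay above 0 in 4 of 4.

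Within monogamous females, muscle genes were higher after mating with promiscuous-line males. The median response was 0.08, the list mean was above 0 in 4 of 4 populations, and 11 of 28 probe sets passed adjusted over the list alone, all higher. By batch the populations agreed less. The muscle list mean of monogamous populations 1 to 4 was 0.16, -0.06, 0.15 and -0.06 in batch 1. In batch 2 it was 0.04, 0.25, 0.01 and 0.26. The sarcomere genes bt, sls, Obsc and Mlp84B responded by 0.28, 0.28, 0.23 and 0.18, with SEs of 0.04 to 0.05, although a second Obsc probe set was at -0.16. Neuronal genes had a median of 0.08 with 6 probe sets past adjusted over the list alone, including Snap25 at 0.20 with an SE of 0.04, the potassium channel gene Sh at 0.24 and Gad1, which makes the transmitter GABA, at 0.14. Other probe sets of Sh lay at -0.12 to 0.25. Antimicrobial peptides had a median of -0.27, and their list mean was -0.28, or -0.11 without population 1. Drsl4 was at -0.40. Camera called 8 lists, with adjusted p-values of 8.3e-09 for muscle, 4.51e-05 for neuronal genes and 3.53e-05 for antimicrobial peptides, against adjusted p-values of 0.368, 0.337 and 0.399 with an estimated correlation. In batch 1 and batch 2 the medians were 0.05 and 0.13 for muscle, 0.09 and 0.02 for neuronal genes, and -0.33 and -0.14 for antimicrobial peptides. The antimicrobial peptide list mean in batch 2 was -1.04 in monogamous population 1 and 0.15 to 0.21 in the other monogamous populations.

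The other 5 lists called in monogamous females were seminal proteins at a median of -0.06, chemosensory receptors at -0.03, phototransduction at 0.03, germline genes at 0.04 and the circadian clock at 0.09. Their adjusted p-values were 0.337 to 0.549 with an estimated correlation. The phototransduction median changed sign between batches, from 0.09 to -0.05, as did that of germline genes, from -0.01 to 0.07. Fry called 2 other lists, sex determination at a median of 0.03 and lipid metabolism at 0.02. The other 3 had medians of -0.06, -0.03 and 0.09 in batch 1 and of -0.05, -0.02 and 0.03 in batch 2. Of single genes limma called 0, with 1588 under an unadjusted p of 0.05, and 0 with the number as a block. The smallest p-values belonged to bt, to the neurogenic gene bib at 0.39 with an SE of 0.06 and to hlk at 0.28 with an SE of 0.04, each with an adjusted p of 0.0943, followed by CG13482 at -0.44 and the transcription factor gene Cf2 at 0.33.

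Within promiscuous females, genes of the cell cycle and DNA replication were higher after mating with promiscuous-line males. All 19 probe sets lay above 0, with a median of 0.09, and 11 passed adjusted over the list alone. The replicative helicase genes Mcm5 and Mcm2 responded by 0.14 each, the replication licensing gene Cdc6 by 0.15 and the cyclin gene CycD by 0.14, with SEs of 0.03 to 0.04. Germline genes were higher by a median of 0.08, including bcd, a maternal determinant of the head, at 0.16. Digestive enzymes were lower by a median of -0.09, with 4 past adjusted over the list alone: Jon99Ci at -0.23 with an SE of 0.03, betaTry at -0.11, Jon25Biii at -0.10 and alphaTry at -0.06. Antimicrobial peptides had a median of -0.19, and their list mean was -0.19, or -0.07 without population 1 and -0.31 without population 2. The camera adjusted p-values were 3.29e-09, 3.48e-07, 5.72e-06 and 0.00388, against adjusted p-values of 0.606, 0.606, 0.606 and 0.77 with an estimated correlation. In batch 1 and batch 2 the medians were 0.14 and 0.04 for cell cycle, 0.12 and 0.02 for germline, -0.12 and -0.06 for digestive enzymes, and -0.12 and -0.15 for antimicrobial peptides. The antimicrobial peptide list mean in batch 2 was -0.85 in promiscuous population 1 and -0.2 to 0.34 in the other promiscuous populations. Fry called lipid metabolism alone, at a median of -0.03.

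CG4830 was the only probe set that limma called in promiscuous females. It fell by 0.31 with an SE of 0.04 (adjusted p = 0.046) and was lower in 4 of 4 populations, with 1917 probe sets under an unadjusted p of 0.05. It was at -0.39 in batch 1 and -0.23 in batch 2, and its adjusted p was 0.0683 with the number as a block. Its responses in promiscuous populations 1 to 4 were -0.56, -0.69, -0.4 and 0.09 in batch 1. In batch 2 they were -0.1, 0.02, -0.26 and -0.61. The populations were thus far apart within each batch, and the small SE holds only for the average of the 2 batches. The call was lost when any of 6 of the 8 populations was left out, and kept without monogamous population 1 or 3. It was also lost in each batch alone, with quantile normalization, centring or arrays as samples, without the dimmest 40% of probe sets and without the intensity trend. Under the block 2 other probe sets passed, Fcp3C at 1.07 with an SE of 0.22 and CG14187 at 0.85 with an SE of 0.14, both with a blocked adjusted p of 0.00583. The Fcp3C responses were 0.27, 1.07, 0.76 and 2.19 in promiscuous populations 1 to 4, and without population 4 their mean was 0.70. The next smallest p-values belonged to Jon99Ci, CG6067 at -0.22, MFS1 at -0.42 and betaTry. Among other list members, the lipid droplet gene Lsd-1 was at -0.20, GstD5 at 0.32 and the serine protease gene CG31681 of the spermatheca list at -0.31, all past their list alone. The chorion gene Cp19 and Femcoat were at -0.85 and -0.82 and also passed their list alone, but in batch 1 they had the opposite direction, at 0.55 and 0.31. CG31681 was at 0.05 in batch 2.

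The third comparison asked whether the response to male regime differed between female regimes. Muscle genes responded less in promiscuous than in monogamous females, with 25 of 28 probe sets lower and a median difference of -0.12. The list mean did not separate all populations. It responded by 0.105 in promiscuous population 2, against 0.085 to 0.102 in the monogamous populations and -0.161 to -0.007 in the other promiscuous populations. The 4 muscle probe sets that passed adjusted over the list alone were bt at -0.27, Obsc at -0.33, sls at -0.29 and Mlp84B at -0.18. Their SEs were 0.05 to 0.07, and a second Obsc probe set was at 0.18. Among markers of other tissues in whole-fly RNA, germline genes were higher in 29 of 40 probe sets (median 0.03, camera adjusted p = 0.116), at 0.14 in batch 1 and -0.04 in batch 2. Yolk and fat body genes were lower in 11 of 12 (median -0.05, adjusted p = 0.0701), at -0.07 and -0.02. Cell cycle genes went the other way, with 18 of 19 probe sets higher, a median of 0.12 and 8 past adjusted over the list alone. Their list mean responded by 0.044 to 0.134 in promiscuous and by -0.062 to 0.051 in monogamous populations. The helicase genes Mcm2, Mcm5 and Mcm3 differed by 0.19, 0.16 and 0.16, and Cdk2 by 0.15. Lipid metabolism genes had a median of -0.06. In that list ACC, which makes malonyl-CoA for fatty acid synthesis, was at -0.17, the fatty acid elongase gene bond at -0.16, Gpdh1 at -0.14 and Lsd-1 at -0.19, all past adjusted over the list alone, although Lsd-1 had the opposite direction in batch 2.

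Camera called 5 lists in the interaction: muscle (adjusted p = 2.15e-08), cell cycle (3.06e-08), phototransduction at a median of -0.06 (0.00221), lipid metabolism (0.0157) and neuronal genes at -0.05 (0.0259). Their adjusted p-values were 0.402, 0.402, 0.402, 0.366 and 0.515 with an estimated correlation. Fry called lipid metabolism alone (adjusted p = 0.00513), and that list had an exact permutation p of 0.0286, the smallest possible, and 0.4 after adjustment over lists. The post-mating switch and ovulation list had the same exact p at a median of -0.03, but camera did not call it (adjusted p = 0.16). Only these 2 lists had an exact permutation p under 0.05 in the interaction, so muscle and cell cycle genes did not reach it. Muscle medians were -0.15 in batch 1 and -0.09 in batch 2, and neuronal medians -0.06 and -0.05. The other 3 differences did not hold in batch 2: the medians of the batches were 0.22 and 0.01 for cell cycle, -0.15 and 0.02 for phototransduction, and -0.09 and 0.02 for lipid metabolism.

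CG4830 was the only probe set called for the interaction. Its response averaged 0.17 ± 0.10 (SD, n = 4) in monogamous and -0.31 ± 0.04 (SD, n = 4) in promiscuous females, a difference of -0.48 with an SE of 0.06 (limma adjusted p = 0.0179), with 1481 probe sets under an unadjusted p of 0.05. The difference was -1.13 in batch 1 and 0.17 in batch 2, the opposite direction. With the number as a block the adjusted p was 0.0946, and limma called 0 probe sets. The call was kept without monogamous population 1 or promiscuous population 2 and lost without any of the other 6. GstD5, a glutathione transferase gene, came next at 0.60 with an SE of 0.09 (adjusted p = 0.0831), with responses of -0.28 ± 0.08 (SD, n = 4) in monogamous and 0.32 ± 0.13 (SD, n = 4) in promiscuous females. It was at 0.97 in batch 1 and 0.23 in batch 2. CG5770 at 0.77, the adenosine deaminase-related growth factor gene Adgf-A at -0.26, MFS1 at -0.51 and Jon99Ci at -0.25 did not pass. Past their own list alone were also Jon99Ci, CG31681 at -0.45 and the small heat shock gene Hsp26 at 0.15, which was at 0.30 in batch 1 and 0.00 in batch 2.

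**Figure D2:**
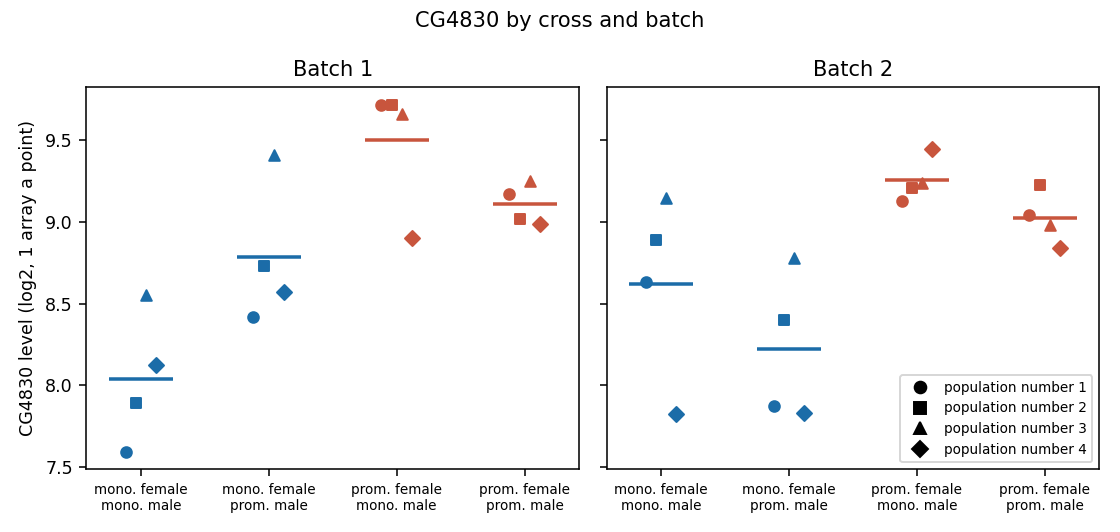
CG4830 level on each array, by cross and batch, on the log2 scale, with a point per array (blue monogamous, red promiscuous females, shape for population number) and a bar for the mean of 4. In batch 1 monogamous females had higher levels with promiscuous-line males, by 0.45 to 0.86, and in batch 2 the same difference was -0.76 to 0.01.

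The last comparison set the promiscuous against the monogamous treatment as they had evolved, with both sexes of the same population. Of 32 eggshell probe sets 18 were higher and 14 lower in the promiscuous crosses, with a median of 0.03 (camera adjusted p = 0.611). Higher members were the vitelline membrane gene Vm32E by 0.50 with an SE of 0.11, the eggshell gene dec by 0.41 with an SE of 0.10, CG14187 by 0.98 with an SE of 0.21 and Fcp3C by 1.20 with an SE of 0.32. These 4 passed adjusted over the list alone. Fcp3C averaged 7.55 ± 0.81 (SD, n = 4) in monogamous and 8.74 ± 0.02 (SD, n = 4) in promiscuous crosses, and its difference was 1.86 in batch 1 and 0.53 in batch 2. Past their own list alone were also tobi at -0.99, daw at 0.39, Desat1 at -0.19, AcCoAS at -0.24, whd, a carnitine palmitoyltransferase gene, at 0.15 and the lipid transfer gene Apoltp at 0.26. The arrays of this comparison are among those averaged in the female comparison, so the 2 are not independent.

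Antimicrobial peptides were lower in the promiscuous crosses, with 19 of 22 probe sets lower and a median of -0.34 (camera adjusted p = 8.53e-05, and 0.923 with an estimated correlation). Fry called no list. The difference of the list mean was -0.37, and -0.15 without monogamous population 1. The exact permutation p was 0.2, no member passed adjusted over the list alone, and the batch medians were -0.34 and -0.30. Phototransduction genes were higher by a median of 0.06 (adjusted p = 0.00225, and 0.89 with an estimated correlation), with batch medians of 0.13 and -0.01. Limma called 0 of the 18769 probe sets, with 1180 under an unadjusted p of 0.05 and a smallest adjusted p of 0.159. With all arrays as samples 15 passed, and 6 passed without monogamous population 1. The smallest p-values belonged to wat at 0.41 with an SE of 0.05, CG42715 at -0.26, CG40485 at -0.89, CG11597 at -0.67 and IscU, an iron-sulfur cluster scaffold gene, at -0.27, none of them past the threshold.

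Between batch 2 and batch 1 of the 16 crosses, 3793 probe sets (20.2%) changed, 2011 higher and 1782 lower, with a median size of 0.14 among them. CG7920 fell by 1.35, Septin1 by 1.00, Fitm by 0.96 and the ATP synthase subunit gene ATPsynbeta by 0.84. CG34348 was at -0.83, and the ribosomal protein gene RpL3 fell by 0.79. The limma adjusted p-values of these genes were 4.45e-12 to 2.17e-09. These genes were named for the size of their change after their values were seen. No term for a batch difference that varied with female regime, male regime or their combination was called by limma (0 probe sets each). Under an unadjusted p of 0.05 lay 1773, 718 and 1422 probe sets, against 938 by chance. The first and last exceed that number, so these counts of 0 do not exclude regime differences that vary with batch.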

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

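The tests of population number 1 and of single batches for the antimicrobial peptide, muscle and cell cycle genes, and the comparison with germline genes, were chosen after the results had been seen. The splits of the samples were planned.

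The response to male regime differed between female regimes for CG4830, by -0.482, and for 5 gene lists. The CG4830 difference was -1.131 in batch 1 and 0.168 in batch 2, the opposite direction, and was not called with the number as a block (adjusted p = 0.0946). The medians of the lists were -0.122 for muscle, 0.119 for cell cycle and replication, -0.055 for phototransduction and eye, -0.06 for lipid metabolism and -0.051 for neuronal genes. All 5 were called at the preset correlation and none with an estimated correlation (camera adjusted p = 0.366 to 0.515). In the fit of responses the estimate was 0.382 for muscle, 0.399 for cell cycle and -0.021 for lipid metabolism. The lipid value lies under the preset 0.01, so a higher correlation does not account for that lost call.

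Muscle genes responded less, and cell cycle genes more, to promiscuous-line males in promiscuous than in monogamous females. For muscle, arrays of batch 1 alone as the source stay open: the difference of the list mean was -0.095 in batch 2 (exact permutation p = 0.286) beside -0.153 in batch 1 (exact permutation p = 0.171), in the same direction but within the spread of the populations. For the cell cycle, the difference was -0.004 in batch 2 beside 0.219 in batch 1 (exact permutation p = 0.0286), which is in line with a pattern of the batch 1 arrays alone. A larger share of ovary RNA could also raise cell cycle genes, and it stays open: the cell cycle list exceeded the germline list by 0.075 (exact permutation p = 0.0857), and the germline list itself had an exact p of 0.457.

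Antimicrobial peptide genes were lower after mating with promiscuous-line males, and the response of edin in monogamous population 1 was -1.28, against -0.27 to -0.17 in the other monogamous populations. The values go against arrays of batch 2 alone as the source, since the list mean was -0.306 in batch 1, lower in 7 of 8 populations (exact sign-flip p = 0.0234), and -0.168 in batch 2, lower in 4 of 8 (exact sign-flip p = 0.445). Turning both responses of a number together gave batch 1 an exact p of 0.125, the smallest possible, so the test cannot exclude it. Population number 1 alone may account for much of it, and this stays open: the mean of the other 6 responses was -0.093 (exact sign-flip p = 0.312). Number 1 lay apart in batch 2, at -1.04 and -0.85 against -0.2 to 0.34 in the others. In batch 1 it did not, at -0.54 and -0.24 against -0.69 to 0.08. Number 1 marks a pair of male populations shared by monogamous and promiscuous females, so a property of those males and a property of the regimes cannot be told apart at this number of populations, and an effect of the males' regime stays open.

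Of 174 groups of 4 populations, 12 held a population far from the other 3, and chance gives this in about 1 in 20 groups, or 8.7 of them. The edin response is given above. For wat, monogamous population 4 lay at 8.81 and the other 3 at 8.95 to 8.97. For CG3609, promiscuous population 1 lay at 10.24 and the others at 10.28 to 10.29. For CG40485, promiscuous population 1 lay at 6.54 and the others at 6.11 to 6.17. The retinin response was -0.2 in promiscuous population 3 and -0.08 to -0.06 in the others. The bt response was 0.21 in promiscuous population 2 and -0.06 to -0.03 in the others. The CG4830 response was -0.26 in promiscuous population 4 and -0.34 to -0.33 in the others. The sls response was 0.1 in promiscuous population 4 and -0.05 to -0.03 in the others. In crosses within populations, Vm32E was at 10.33 in monogamous population 2 and at 10.12 to 10.15 in the others, and daw was at 7.93 in monogamous population 3 and at 7.8 to 7.81 in the others. The mean level of the germline list was 9.53 in monogamous population 1 and 9.58 in the other 3. The phototransduction list mean responded by 0.02 in promiscuous population 4 and by -0.05 to -0.04 in the others.

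Counts of calls were compared with those of other splits of the same values. Chance could be excluded for the batch difference: 1 of 100 splits, the real one, gave 3793 probe sets, and the highest other gave 339. Chance could not be excluded for the interaction, where 6 of 35 splits gave as many as the real 1 and the highest other gave 3, or for gene lists. There 30 of 35 splits gave as many as the real 2 in the female regime (highest other 13), 9 of 100 as many as the real 9 in the male regime (highest other 12) and 17 of 35 as many as the real 5 in the interaction (highest other 8). A real count of 0 is reached by every split, so for those comparisons the splits say nothing about chance: 35 of 35 for the female regime (highest other 33), 35 of 35 for the crosses within populations (highest other 12) and 100 of 100 for the male regime over both female regimes (highest other 6). With all 32 arrays as samples, 2 of 35 splits gave as many as the real 142 for the female regime, so chance could not be excluded. The other was monogamous population 1 with promiscuous populations 1, 2 and 4 against the rest, with 256.

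The responses allow 8 sign patterns within a female regime, too few for a share under 0.05. In monogamous females the real count was 0, which all 8 of 8 reach by construction, and the highest other gave 3. In promiscuous females 1 of 8 gave the real 1 and the highest other gave 0. With the number as a block and both responses of a number turned together, 4 of 8 patterns gave as many as the real 13, and the highest other gave 25. These 8 patterns are too few as well.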

How the results depend on the processing

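The alternatives without population number 1, with responses averaged per number, and with each population left out of the antimicrobial peptide list mean, were chosen after the results had been seen, and all others were planned. Over the named genes, and the lists called for the female regime, the male regime over both female regimes and the interaction, 2047 values under an alternative kept their direction and their side of the threshold, 46 newly passed, 79 no longer passed and 9 had the opposite direction. For named genes this threshold was the adjusted p over all probe sets, which only CG4830 passed in the main fits. Staying uncalled therefore counts as the same side for the other genes. Whether they still passed adjusted over the list alone was not followed. The 9 values with the opposite direction came from arrays of a single batch. In batch 1 the muscle median for male regime was -0.02, and in promiscuous females the male response was 0.552 for Cp19 and 0.314 for Femcoat. In batch 2 the male response of CG31681 in promiscuous females was 0.048, and the interaction was 0.168 for CG4830, 0.125 for Lsd-1, 0.02 for phototransduction, 0.022 for lipid metabolism and 0.007 for cell cycle genes. For the last list the mean was -0.004 and camera's direction was down, so median and mean differed in sign. Lists called in the other comparisons were followed by batch alone. There the phototransduction median was -0.049 in monogamous females and -0.007 in the crosses within populations in batch 2, and the germline median in monogamous females was -0.01 in batch 1. A single batch leaves 1 array per cross, and apart from this construction the cause was not tested.

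For the female regime (0 calls) the count was 1 in batch 1, which was wat, 142 with all 32 arrays as samples and 169 with array weights, where arrays and not populations are the samples. It was 0 to 1 when each population was left out, with 1 without monogamous population 4. For the male regime over both female regimes (0 calls) the count was 13 with the number as a block, 0 with the responses averaged per number, and 0 to 2 over the left-out populations, with 2 without monogamous population 3 and 1 without monogamous population 4. In monogamous females (0 calls) it was 5 at a threshold of 0.1, and 0 to 10 over the left-out populations, with 10 without promiscuous population 2 and 1 without promiscuous population 4. These populations enter through the shared variance estimate. Within the crosses of a single population (0 calls) the count was 1 with the number as a block, 15 with arrays as samples, 17 with array weights and 1 without number 1. It was 0 to 6 over the left-out populations, with 6 without monogamous population 1.

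In promiscuous females (1 call) the count was 2 at a threshold of 0.1 and 2 with the number as a block, which share 1 and 0 probe sets with the main result. It was 0 in either batch alone, with quantile normalization, with centring, without the dimmest 40% of probe sets, without the trend, with arrays as samples, with array weights and without number 1. It was 0 to 2 over the left-out populations: 2 without monogamous population 3, 1 without monogamous population 1 and 0 without any of the other 6. For the interaction (1 call) the count was 2 at a threshold of 0.1, 2 in batch 1 and 2 with centring, each including CG4830, and 0 in batch 2, with the number as a block, without the trend, with arrays as samples and with array weights. It was 0 to 4 over the left-out populations, with 4 without promiscuous population 2, 1 without monogamous population 1 and 0 without any of the other 6. The batch count was 2261 to 2759 when a population number was left out, the lowest without number 1. Without number 2 it was 2521 and without number 4 it was 2499. Fewer samples were fitted in each.

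For gene lists in the female regime (2 calls) the count was 1 in batch 1, 4 in batch 2, 4 with the number as a block, 0 with an estimated correlation, 0 with fry and 4 without number 1. It was 2 to 5 over the left-out populations, with 5 without monogamous population 1 and 4 without monogamous population 3 or promiscuous population 1. For lists in the male regime (9 calls) it was 0 with an estimated correlation, 1 with fry and 15 without number 1, which kept all 9, and 8 to 12 over the left-out populations. For lists in the interaction (5 calls) it was 3 in batch 2, 0 with an estimated correlation, 1 with fry and 3 without number 1. It was 3 to 7 over the left-out populations, with 3 without monogamous population 3. The cause of these changes was not tested. Apart from the counts given here, no count crossed its threshold with the number as a block. The median difference of all probe sets in the female regime was 0.004, and -0.002 with quantile normalization and -0.007 with centring, and signals near the background level limit what weak probe sets can show.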

Other observations

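The comparison among populations of a regime, the comparison among population numbers and the tests of the first were not planned. Those tests were written down before their results were seen. Females of populations that shared a regime differed from each other in many genes. Each female population was mated only to males of its own number, so differences among females and among their mates cannot be told apart here. Among the 4 monogamous populations limma called 2542 probe sets (13.5%) and among the 4 promiscuous populations 1849 (9.9%). Of these 973 were called in both, against 250 if the 2 sets of calls were independent. Both sets share 1 variance estimate per probe set, and bright probe sets are called more often, so some excess is built in. The arrays of a population are repeat measurements of it, so these counts cannot be ranked against those for regime, which rest on the spread between populations. CG6765 was at 3.42 in monogamous population 1 and at 6.64 to 8.81 in the other 7. The cytochrome P450 gene Cyp12d1-d was at 4.29 in monogamous population 3 and 5.33 in promiscuous population 3, and at 6.21 to 8.58 elsewhere. The antimicrobial peptide gene DptB was at 10.54 in monogamous population 1, 8.87 in promiscuous population 1 and 6.86 to 7.75 in the rest. RalGPS, a regulator of a small GTPase, ranged over 3.07 among monogamous and 2.83 among promiscuous populations, and the P450 gene Cyp4d21 was at 7.21 in promiscuous population 2 and 3.96 in promiscuous population 3.

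These differences were more frequent in some gene lists than in others. Digestive enzymes were called in 39 of 44 probe sets (88.6%, Fisher's exact adjusted p = 8.07e-20), glutathione transferases in 29 of 36 (80.6%, 9.89e-13) and cytochrome P450 genes in 48 of 83 (57.8%, 6.24e-12), against 21.6% of all probe sets with a single gene. Circadian clock genes were called in 9 of 13 (69.2%), spermatheca genes in 12 of 21 (57.1%), muscle genes in 15 of 28 (53.6%) and odorant-binding proteins in 22 of 55, and UDP-glycosyltransferases in 14 of 35 (adjusted p = 0.0269). Proteasome genes were called in 1 of 40 (adjusted p = 0.00523) and ribosomal protein genes in 2 of 47 (0.00626). Chemosensory receptors were called in 11 of 186 (3.34e-08) and seminal protein genes in 1 of 30 (0.0269), but only 1 and 4 of their probe sets were among the brighter. Among brighter probe sets, where 30.8% were called, the shares were 37 of 42, 26 of 30 and 44 of 59 for the first 3 lists and 0 of 26 and 1 of 38 for the proteasome and ribosomal proteins. The clock, spermatheca, muscle and odorant-binding lists also passed there, and UDP-glycosyltransferases did not (0.139). Yolk and fat body, lipid metabolism, antimicrobial peptide and immune recognition lists passed over all probe sets (Fisher's exact adjusted p = 0.0155 to 0.0303). Among the brighter they did not (0.14 to 0.336). Probe sets of a list are not independent of each other.

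Chance differences between arrays were argued against for these population differences: over the 1335 probe sets called in batch 1 alone, the 8 population deviations correlated between batches at a median of 0.84 (95% bootstrap interval 0.83 to 0.85), against 0.29 over all probe sets. Sequence variants under a probe may account for part and stay open, since a second probe set of the same gene correlated at a median of 0.39 (95% bootstrap interval 0.23 to 0.55, 174 pairs), against 0.02 for a random partner. Neighbouring called genes correlated at a median of 0.13 over 836 pairs, against at most 0.09 in random pairs (permutation p = 1e-04, the smallest that 10000 draws can give), and at 0.11 over 755 pairs with different name stems. This is in line with linked variants or shared control of neighbours as a hypothesis. Drift and selection could not be separated with these values.

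By limma the responses to male regime differed among population numbers in 21 probe sets, with 789 under an unadjusted p of 0.05 against 938 by chance. The population means differed in 0, with 1057 under an unadjusted p of 0.05. BomBc2 responded by -1.68 in monogamous and -1.76 in promiscuous females of number 1, by -0.47 and 0.44 in number 2, by 0.57 and 0.53 in number 3 and by -0.77 and -0.75 in number 4. The splicing regulator gene sm responded by -0.39 and -0.34 in number 1 and by 0.43 and 0.45 in number 2.

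Several groups that mating is known to engage were not called by camera in any of the 6 comparisons. For the female regime the medians were 0.02 for eggshell genes (adjusted p = 0.593), 0.02 for yolk and fat body (0.534), 0.01 for the post-mating switch and ovulation (0.852), 0.01 for the spermatheca (0.593) and -0.01 for juvenile hormone and ecdysone (0.673). For the male regime over both female regimes the same lists were at 0.01 (0.911), 0.01 (0.608), 0.00 (0.79), -0.01 (0.659) and 0.02 (0.298). Insulin and nutrient signalling was at -0.06 for the female regime (0.0745) and 0.00 for the male regime (0.79). In the interaction the post-mating switch and ovulation list mean had an exact permutation p of 0.0286 (0.0286 in batch 1 and 0.971 in batch 2). Egg yolk gene Yp2 was at 0.11 for the female regime and did not pass.

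The other lists that camera never called were as follows for the female and then the male regime, with adjusted p-values of 0.157 to 0.822 for the female and 0.0522 to 0.79 for the male regime. Immune recognition was at 0.00 and -0.01, Turandot and heat shock genes at 0.00 and 0.01, testis and sperm genes at 0.03 and -0.02, and odorant-binding proteins at 0.03 and -0.01. Cytochrome P450 genes were at 0.02 and -0.01, glutathione transferases at 0.05 and -0.01, and UDP-glycosyltransferases at 0.04 and -0.02. Ribosomal proteins were at 0.01 and -0.01, the proteasome at 0.00 in both, and sex determination at -0.01 and 0.03.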
